A study of Mus musculus with 21 samples.

How the data were processed

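Livers of 24 adult male C57BL/6J mice were studied by the authors, and the arrays of 3 mice were excluded by them for uneven hybridisation, per the labels. After 3 weeks of adaptation on a normal-fat diet the mice ate a high-fat diet for 12 weeks, without quercetin (HF) or with 0.33% (w/w) quercetin (HF-Q), and were fasted for 2 to 4 hours before tissue was taken, per the labels. From 200 ng of RNA per mouse, 1 liver was labelled with Cy5 and an equimolar pool of all samples with Cy3 on each 2-colour Agilent mouse array, per the labels. The 21 arrays held 11 HF and 10 HF-Q livers, no dyes were swapped, and no pair of arrays was identical.

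The authors deposited the scanner output of each array, whose mean spot intensity and local background intensity in both channels are not normalized, per the file headers. Agilent Feature Extraction 10.7.3.1 made these files, per the submitters' processing notes, and its processed intensity columns are background-subtracted and dye-normalized, per the file headers. Flags of 0 or 1 for spots well above background, saturated or uneven come from the same software, per the file headers. The authors also deposited a table of log2 values, 1 column per array. Set against the scanner files, its columns correlated with the log2 Cy5 signal at r = 0.985 to 0.999 and with the Cy3 signal at 0.980 to 0.992, and every column had a median of 7.92. The step that made these medians equal is not given in the sources used here, so the table served only as an alternative.

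Each array held 62976 spots, 3671 of them controls, and 55681 probes. Background was corrected with normexp (offset 50) and the ratio of Cy5 to Cy3 was normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots and spots marked uneven or outlying at weight 0. Those spots were then left out, saturated spots were kept, and spots of a probe were averaged. A probe was kept if its Cy5 signal was well above background on at least 10 of 21 arrays, which left 26291 probes, and the brightest probe stood for a gene, which gave 19718 genes, 4866 of them with several kept probes. The pool is in every array, so log2 ratios are relative to it, and normexp with an offset draws the ratios of dim genes toward 0.

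Gene names are those of the array files, updated through RefSeq accessions to the symbols of the GRCm38.p6 annotation for 27235 probes, which changed the name of 1323 tested genes. Of the tested genes, 14448 had a symbol. Probe coordinates are those of the array files on mouse build NCBI37 (mm9), and the annotation was used for names only.

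Between 44.2% and 51.3% of probes were well above background in Cy5 (median 47.5%), and the median Cy5 signal was 64.5 to 74.8 against a background of 33 to 36. Log2 ratios of pairs of arrays correlated across genes at r = 0.030 to 0.63. The median residual SD of a gene was 0.13.

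HF-Q was compared with HF by limma's moderated test on log2 ratios, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists with at least 5 measured members were tested with camera at its preset correlation of 0.01 on the 19230 genes with a value on all arrays, adjusted over 36 lists, with camera at an estimated correlation and fry beside it. The groups, tests, 36 lists, naming rule and all alternatives not described as chosen later were fixed before the data were examined. The rule named the 8 genes per direction with the largest change past the threshold, filled up with those of lowest p where fewer passed, as all were here, and up to 4 members of lowest p per list. It also named a panel of 15 genes whatever their result. Only names that are gene symbols were taken under its first part, and a gene outside the rule is said to be so. Some genes that the rule names are not reported here one by one, but they stayed in the tests, counts and lists, except in the search for single livers far from their group.

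The test was tested on simulated data for HF-Q against HF, with 19718 genes of the measured spread, 200 of them changed, 50 per size. The simulated values were independent between genes and the changed genes were picked at random. It recovered 72% at a log2 change of 0.25, 94% at 0.5 and 100% at 1 and 1.5. Among the calls 0.543% were false, and 0 calls were made when nothing was changed. With 200 genes changed at once the adjustment is less strict than where few genes or none pass.

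Alternatives changed the background correction, the normalization within and between arrays, the use of the reference channel, the filter on dim probes, the choice of probe, the variance model, array weights, the threshold and the list test. Slide and row on the slide were used as blocks, each slide was fitted alone, replicate numbers were used as a block, and each array was left out in turn. Fits with fewer arrays took every list member measured on all of those arrays, so a list could hold more members than in the full comparison, whereas the list medians given for each slide in the results are over the members of the full comparison. Scan sessions coincided with the 3 slides, so a separate block for them was not run.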

Results

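Liver RNA was measured from 21 adult male mice of the inbred strain C57BL/6J after 12 weeks on a high-fat diet, either alone (HF, 11 mice) or with quercetin, a plant flavonoid, added at 0.33% of diet weight (HF-Q, 10 mice). Each mouse was hybridised to 1 array, its RNA in the Cy5 channel against a pool of all livers in the Cy3 channel, so every value is a log2 ratio of a liver to that pool. The arrays lay on 3 slides that each held both groups. Slide 1 carried 3 HF and 4 HF-Q arrays, slide 2 carried 4 and 2, and slide 3 carried 4 and 4. Between 44.2% and 51.3% of the probes were well above background in the liver channel of an array, and 19718 genes were tested. The comparison of HF-Q with HF asks how dietary quercetin alters hepatic gene expression under a high-fat diet. The number of arrays limits its precision.

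Expression of Cyp2b10, the classical target gene of the xenobiotic receptor CAR, was 2.53 times lower in HF-Q than in HF livers (log2 fold change -1.34 ± 0.33, SE, n = 10 and 11). Its log2 ratio to the pool averaged -1.09 ± 0.70 (SD) in HF-Q and 0.25 ± 0.95 in HF. Its relatives Cyp2b9 and Cyp2b13 had log2 fold changes of -0.76 ± 0.21 and -0.75 ± 0.19 (SE). Cyp2b9 was well above background in 10 of 11 HF and 2 of 10 HF-Q livers, and Cyp2b13 in 10 of 11 and 1 of 10. None of the 3 differences passed the threshold over all genes in limma (adjusted p = 0.515 for Cyp2b10 and Cyp2b13, and 0.685 for Cyp2b9; unadjusted p = 5.38e-04, 5.95e-04 and 0.00145). One liver of each group lay on the other group's side for all 3 genes. Cyp2b10 stood at -1.96 in HF replicate 2, with the other HF livers at -0.10 or above, and at 0.62 in HF-Q replicate 10, with the other HF-Q livers at -0.91 or below. Without HF replicate 2 the log2 fold change of Cyp2b10 was -1.56, past the threshold (limma adjusted p = 0.0443). With the slide as a block it was -1.42, and within slides 1, 2 and 3 it was -1.90, -1.56 and -0.93. The dim genes Cyp2b9 and Cyp2b13 differed by -2.76 and -2.38 in the signals as processed by the scanner software. The Cyp2b10 probe lies on chromosome 7 at 26711522 to 26711581, the Cyp2b13 probe at 26880905 to 26880964 and the Cyp2b9 probe at 26983484 to 26983543 of mouse build NCBI37, and cross-hybridisation among these similar genes was not tested.

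**Figure D1:**
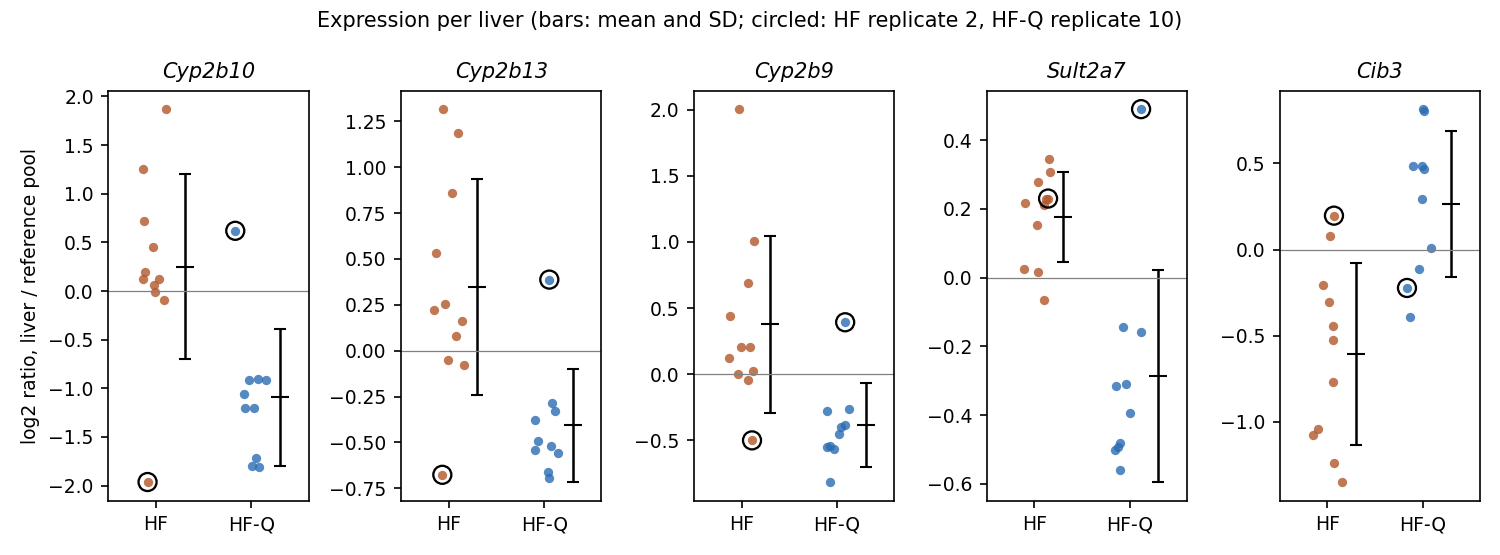
Log2 ratio of each liver to the reference pool (vertical axis) for 5 genes in the HF and HF-Q groups, with 1 point per liver, the group mean and SD as bars, and HF replicate 2 and HF-Q replicate 10 circled. For Cyp2b10 these livers stand at -1.96 and 0.62, each on the other group's side, while for Sult2a7 HF-Q replicate 10 does, at 0.49, and HF replicate 2 does not, at 0.23.

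The Cyp2b genes were named through the panel and the lists, and were not among the 8 genes of lowest p in either direction. Of those, Cib3, a member of the calcium and integrin binding family, had the largest difference, 1.83 times higher in HF-Q (log2 fold change 0.87 ± 0.19, SE). Pdia5, a disulfide isomerase of the endoplasmic reticulum, differed by 0.24 ± 0.06 and Pde6d, a carrier of prenylated proteins, by 0.17 ± 0.04. Differences of 0.14 to 0.20 were measured for Porcn, which acylates Wnt proteins, Gcat, an enzyme of threonine breakdown, the pseudogene Selenok-ps1 and the predicted gene Gm10701. On the lower side, Sult2a7, a sulfotransferase, had a log2 fold change of -0.46 ± 0.09, the transcription factor gene Cebpe one of -0.27 ± 0.05 and the predicted gene Gm2990 one of -0.25 ± 0.05. Gm3515, Eda, which encodes ectodysplasin, and Adgrl1, an adhesion receptor gene, had values between -0.26 and -0.20. In the signals as processed by the scanner software Gm10701, Gm2990, Eda and Adgrl1 stood at 0.52, -0.73, -0.46 and -0.49, and Gm3515 was -0.50 with a smaller normexp offset and -0.090 from Cy5 alone. Sult2a7 passed the threshold without HF-Q replicate 10, at -0.55 (limma adjusted p = 1.45e-04), and was -0.15, -0.75 and -0.56 on slides 1, 2 and 3. The 8 genes of lowest p in each direction all kept it within each of the 3 slides and with the slide as a block, but they were picked on the same arrays, which favours 1 sign on every slide, so this is no independent sign of stability.

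No gene passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment over 19718 genes, and the lowest adjusted p was 0.382. At an unadjusted p under 0.05 there were 1169 genes, 596 higher and 573 lower in HF-Q, against 985.9 that chance gives. Without HF replicate 2, 4 genes passed: Cyp2b10, the fatty acid binding protein gene Fabp5 (0.81) and the unnamed transcripts NAP111439-1 (0.87) and NAP114472-1 (0.81), the last 3 named after their values were seen. Those 3 had close values, at 0.99, 1.17 and 1.02 in HF replicate 2, so they may not be 3 independent signals. Without HF-Q replicate 10 the count of genes passing was 1, Sult2a7, and without both, an exclusion made after seeing the Cyp2b values, it was 18, again with those 3 among them. Of simulated genes that differed by 0.25, 0.5 and 1 on the log2 scale with the measured spread, 72%, 94% and 100% were recovered. These were randomly chosen genes with independent values. The recovery does not hold for genes as variable as Cyp2b10, which did not pass at -1.34, nor for variation that livers share across genes. It also rests on 200 genes changed at once, since Benjamini-Hochberg adjustment is less strict the more genes pass. Where few genes differ, recovery would be lower, and Cib3 at 0.87 and Cebpe at -0.27 did not pass here.

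Of the 15 genes named in advance as a panel, Nr1i3, which encodes CAR, differed by -0.18 ± 0.06 (SE; limma adjusted p = 0.771) and Ppara, the nuclear receptor gene of fatty acid breakdown, by -0.23 ± 0.10 (limma adjusted p = 0.821). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.37 ± 0.40. The lipogenic genes Fasn, Scd1 and Srebf1 differed by 0.11 ± 0.17, -0.20 ± 0.14 and -0.079 ± 0.141, and the fatty acid transporter Cd36 by -0.27 ± 0.23. For Cyp4a10, Cyp4a14 and Cpt1a, which respond to fatty acids through PPAR-alpha, the differences were -0.11 ± 0.14, 0.10 ± 0.34 and -0.12 ± 0.07. With 1 array left out Cyp4a14 turned to -0.076 without HF replicate 2, -0.013 without HF replicate 4 and -0.063 without HF-Q replicate 7, and ranges of other panel genes were 0.19 to 0.60 for Cyp7a1, 0.017 to 0.18 for Fasn, -0.25 to -0.12 for Scd1, -0.16 to -0.028 for Srebf1, -0.43 to -0.21 for Cd36 and -0.18 to -0.039 for Cyp4a10. Por, the reductase that serves the P450 enzymes, Cyp1a1, a target of the aryl hydrocarbon receptor, and Nqo1, an antioxidant enzyme, differed by -0.065 ± 0.185, -0.020 ± 0.063 and -0.022 ± 0.078. The Por value ranged from -0.15 to -0.0011 with 1 array left out, Cyp1a1 turned to 0.026 without HF replicate 9 and 0.0030 without HF-Q replicate 1, and Nqo1 to 0.0057 and 0.0075 without HF-Q replicate 3 and 4. Apart from Cyp2b10, Nr1i3 and Ppara, none of the 15 reached an unadjusted p under 0.05. Of the 15, 7 kept their direction within each slide. The others turned to -0.019 (Cyp7a1), 0.12 (Nqo1), 0.025 (Cyp1a1) and -0.36 (Cyp4a14) on slide 1, to 0.028 (Ppara) and -0.49 (Cyp4a14) on slide 2, and to -0.013 (Fasn), 0.34 (Por), 0.057 (Cyp4a10) and 0.094 (Cyp1a1) on slide 3.

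Genes of cholesterol synthesis rose as a group in HF-Q: 22 of 23 measured members were higher, with a median log2 fold change of 0.27. The shift passed camera with its preset correlation (adjusted p = 2.72e-12) and not with the correlation estimated from the arrays (adjusted p = 0.261 with an estimated correlation). The pathway enzymes Fdps, Pmvk and Mvk had log2 fold changes of 0.40 ± 0.14, 0.36 ± 0.13 and 0.28 ± 0.11 (SE). The mean of the list per liver was 0.11 ± 0.16 (SD, n = 10) in HF-Q and -0.12 ± 0.30 (n = 11) in HF, so the groups overlapped. Of the members, 12 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone or over all genes. The median was 0.27 with the slide as a block and 0.36, 0.31 and 0.098 on slides 1, 2 and 3.

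**Figure D2:**
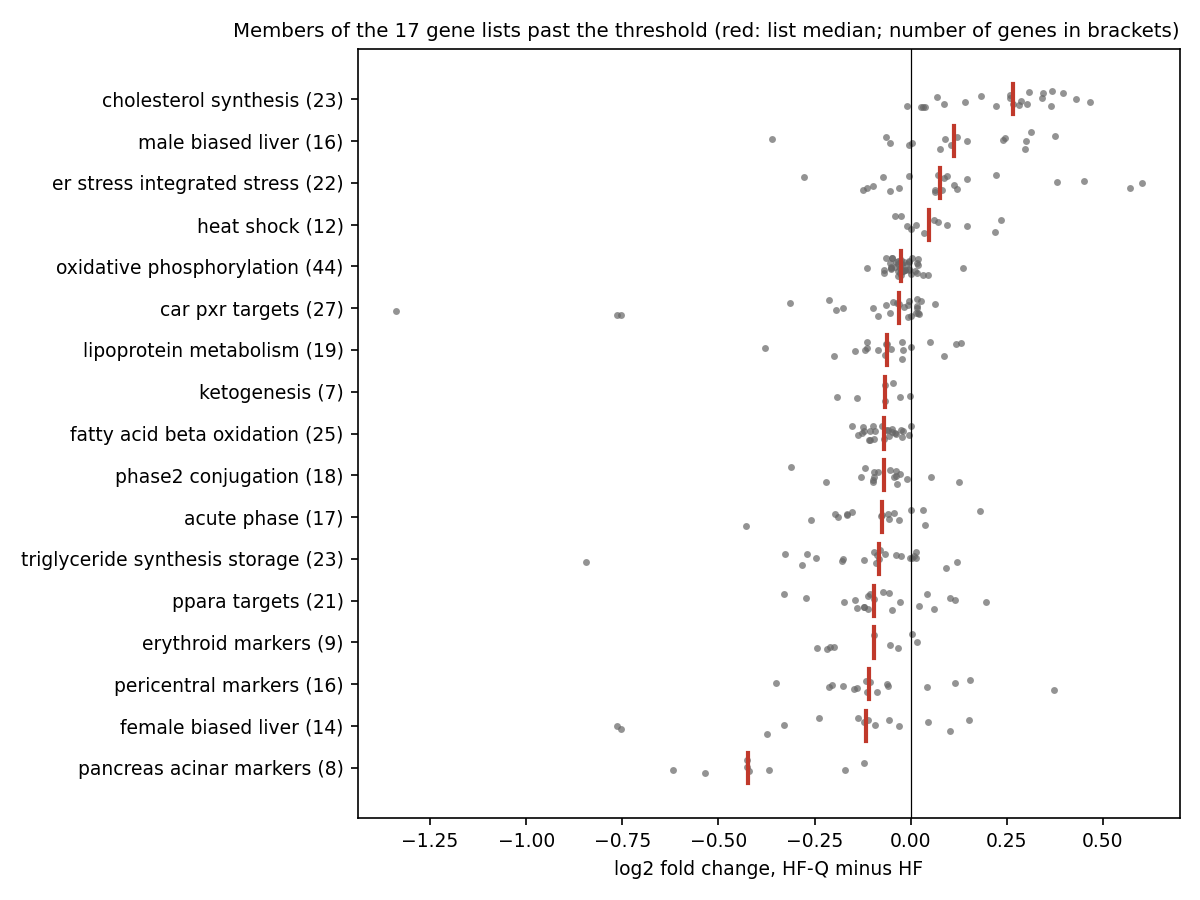
Log2 fold change (HF-Q minus HF, horizontal axis) of each measured gene in the 17 gene lists that passed camera with its preset correlation, with the list median as a red bar and the number of genes in brackets. The cholesterol synthesis genes lie at a median of 0.27, with 22 of 23 above 0, while the medians of the oxidative phosphorylation, lipoprotein, and CAR and PXR lists change sign with median centring, to 0.045, 0.023 and 0.022.

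Genes of fatty acid breakdown were lower in HF-Q by small amounts. Of 25 beta-oxidation genes, 24 were lower, with a median of -0.069 (camera adjusted p = 7.21e-07; adjusted p = 0.191 with an estimated correlation), among them Hadh (-0.15 ± 0.05, SE), Acaa2 (-0.095 ± 0.036), Decr1 (-0.13 ± 0.06) and Etfdh (-0.11 ± 0.05). All 7 ketogenesis genes were lower, at a median of -0.066 (camera adjusted p = 0.00446; adjusted p = 0.191 with an estimated correlation), and 2 passed when adjusted over the list alone, among them Bdh1 (-0.19 ± 0.05), a dehydrogenase of ketone bodies. Of 21 targets of PPAR-alpha, 15 were lower at a median of -0.095 (camera adjusted p = 0.00711; adjusted p = 0.465 with an estimated correlation), with Aldh3a2, a fatty aldehyde dehydrogenase, at -0.17 ± 0.08 and Vnn1, a pantetheinase, at -0.27 ± 0.14. With the slide as a block the medians were -0.068, -0.064 and -0.094. On slides 1, 2 and 3 they were -0.12, -0.055 and -0.035 for beta-oxidation, -0.021, -0.053 and -0.080 for ketogenesis, and -0.13, -0.053 and -0.040 for PPAR-alpha targets, and Acaa2 turned to 0.022 on slide 2. With median centring all 3 lists lost the call, at medians of -0.010, -0.011 and -0.023. The PPAR-alpha call was lost without HF replicate 5 (adjusted p = 0.0694, median -0.063) or HF-Q replicate 1 (0.0538, median -0.060), and without HF replicate 6 its median was -0.054.

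Among xenobiotic genes, 18 of 27 targets of CAR and PXR were lower, at a median of -0.030 that was 0.022 with median centring (camera adjusted p = 0.00215; adjusted p = 0.261 with an estimated correlation). Besides the 3 Cyp2b genes, Cyp3a25 (-0.31 ± 0.09, SE), Aldh1a1 (-0.21 ± 0.07) and Nr1i3 passed when adjusted over the list alone, 6 genes in all. The call was lost without the 3 Cyp2b genes (adjusted p = 0.0700, median -0.012), a check chosen after seeing the data. The median was -0.057 without HF replicate 1, -0.0093 without HF replicate 6, -0.017 without HF replicate 9 or HF-Q replicate 4, -0.012 without HF-Q replicate 3 and -0.045 without HF-Q replicate 8. Of 18 phase 2 conjugation genes, 16 were lower at a median of -0.069 (camera adjusted p = 0.00651; adjusted p = 0.191 with an estimated correlation). Sult1c2, at -0.31 ± 0.08, passed when adjusted over the list alone, and Ugp2 was at -0.22 ± 0.09. That median was -0.036 without HF-Q replicate 7 (-0.030 with the 19 members measured on the other 20 arrays), and the call was lost with median centring (median -0.011). With the slide as a block the 2 medians were -0.024 and -0.083. On slides 1, 2 and 3 they were -0.082, -0.048 and -0.0017 for CAR and PXR targets and -0.036, -0.055 and -0.055 for conjugation.

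Sex-biased liver genes moved in opposite directions. Of 14 female-biased genes, 11 were lower in HF-Q at a median of -0.12 (camera adjusted p = 0.00129; adjusted p = 0.261 with an estimated correlation), and Cyp2b13, Cyp2b9 and the peroxisomal oxidase gene Hao2 (-0.37 ± 0.12, SE) passed when adjusted over the list alone. The dim gene Hao2 stood at -1.39 in the signals as processed by the scanner software and at -0.59 in the deposited values. Without the Cyp2b genes that list still passed (camera adjusted p = 0.0386, median -0.10), a check chosen after seeing the data. Of 16 male-biased genes, 12 were higher at a median of 0.11 (camera adjusted p = 0.00913; adjusted p = 0.469 with an estimated correlation), with Mup20, a major urinary protein, at 0.37 ± 0.17, the complement gene C6 at 0.25 ± 0.13 and Cyp7b1 at 0.24 ± 0.14. The slide block gave medians of -0.13 and 0.11. Slides 1 and 2 gave -0.32 and -0.31 for the female-biased list and 0.23 and 0.24 for the male-biased one, and slide 3 reversed both, at 0.077 and -0.093. Slide 3 holds HF replicate 2, and without that liver the male-biased median over all slides was 0.20. Slide 3 was not fitted without it. The other HF livers of slide 3 had male-biased list means of 0.14, -0.018 and 0.015. Its HF-Q livers had 0.093, 0.0045, -0.092 and 0.059, so these overlapped. The male-biased call was lost without HF replicate 5 (adjusted p = 0.0659, median 0.086) or HF-Q replicate 1 (0.0596, median 0.072), and without HF replicate 3 the median was 0.071.

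Genes of the endoplasmic reticulum and integrated stress responses and heat shock genes were higher. Of 22 stress response genes, 14 were higher at a median of 0.076 (camera adjusted p = 0.00855; adjusted p = 0.261 with an estimated correlation). The members with the lowest p belong to protein folding and degradation in the endoplasmic reticulum: Creld2 (0.45 ± 0.13, SE), which passed when adjusted over the list alone, Derl3 (0.57 ± 0.19), Sdf2l1 (0.38 ± 0.14) and the chaperone gene Hspa5 (0.22 ± 0.09). Of 12 heat shock genes, 9 were higher at a median of 0.048, with Hsph1 at 0.22 ± 0.08 and Hspb1 at 0.23 ± 0.09 (camera adjusted p = 0.00971; adjusted p = 0.317 with an estimated correlation). The medians were 0.090 and 0.054 with the slide as a block. Across all settings other than single arrays left out, they ran from -0.030 to 0.13 and from 0.033 to 0.091. On slides 1, 2 and 3 they were 0.090, 0.054 and -0.028 for stress response genes and 0.050, 0.043 and 0.065 for heat shock genes, and Hspa5 turned to -0.084 on slide 3. The heat shock call was lost without HF-Q replicate 5 (adjusted p = 0.0551, median 0.037) or HF-Q replicate 6 (0.0506, median 0.038), and the median was 0.030 without HF replicate 1.

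Acute-phase genes, which encode plasma proteins of inflammation, were lower in HF-Q for 13 of 17 members at a median of -0.074 (camera adjusted p = 6.11e-04; adjusted p = 0.191 with an estimated correlation). The orosomucoid genes Orm2 and Orm3 differed by -0.20 ± 0.07 and -0.26 ± 0.10 (SE), and Saa4 by -0.17 ± 0.06. The list mean per liver was -0.56 ± 0.09 (SD, n = 10) in HF-Q and -0.46 ± 0.10 (n = 11) in HF, so livers of both groups lay below the pool. The median was -0.087 with the slide as a block and -0.10, -0.080 and -0.11 on slides 1, 2 and 3. Across all settings other than single arrays left out it ran from -0.11 to -0.020, and the camera adjusted p reached 0.805, so the call was not kept in all. Of 16 pericentral markers, genes of hepatocytes around the central vein, 12 were lower at a median of -0.11 (camera adjusted p = 0.00691; adjusted p = 0.386 with an estimated correlation), and Lect2 was at -0.15 ± 0.06 while Cyp27a1 was at 0.11 ± 0.05. Their median was -0.12 with the slide as a block and -0.065, -0.054 and -0.15 on slides 1, 2 and 3, and Lect2 turned to 0.043 on slide 1. Their call was lost without HF-Q replicate 7 (adjusted p = 0.0674, median -0.082) and with median centring (median -0.048).

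Lipid and mitochondrial lists shifted by small medians. Of 23 genes of triglyceride synthesis and storage, 17 were lower at a median of -0.083 (camera adjusted p = 0.0134; adjusted p = 0.465 with an estimated correlation), with the lipid droplet genes Cideb at -0.091 ± 0.044 (SE) and Cidea at -0.84 ± 0.52. Of 19 lipoprotein genes, 14 were lower at a median of -0.062 (camera adjusted p = 0.0310; adjusted p = 0.386 with an estimated correlation), though it was 0.023 with median centring, with Apoc2 at -0.20 ± 0.07, Apoa4 at -0.38 ± 0.17 and Apoa1 at 0.12 ± 0.07. Of 44 oxidative phosphorylation genes, 34 were lower at a median of -0.024 (camera adjusted p = 0.0104; adjusted p = 0.553 with an estimated correlation), with Atp5a1 at -0.11 ± 0.04, but the median was 0.045 with median centring and 0.013 in the authors' deposited values. With the slide as a block the medians were -0.083, -0.067 and -0.022. On slides 1, 2 and 3 they were -0.11, 5.76e-04 and -0.10 for triglyceride storage, -0.034, 0.020 and -0.13 for lipoproteins, and 0.015, -0.072 and -0.014 for oxidative phosphorylation, and Cidea was 0.10, -0.59 and -2.13. The triglyceride call was lost without HF replicate 3, 5 or 7 or HF-Q replicate 3 or 4 (adjusted p between 0.0508 and 0.0942). The lipoprotein call was lost without HF replicate 3, 4 or 7 or HF-Q replicate 4, 7 or 10 (0.0589 to 0.132), with a median of -0.041 without HF-Q replicate 7. The oxidative phosphorylation call was lost without HF replicate 1, 4 or 10 or HF-Q replicate 1 (0.0506 to 0.166), with medians of -0.015 without HF replicate 1, -0.014 without HF replicate 10 and -0.037 without HF replicate 2.

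Markers of other cells differed as well. The 8 acinar genes of the pancreas were lower in HF-Q at a median of -0.42 (camera adjusted p = 0.00711; adjusted p = 0.469 with an estimated correlation), which rested on 2 HF livers of slide 1. The list mean was 1.57 in HF replicate 5 and 2.17 in HF replicate 11, -0.28 in HF replicate 7, -0.11 in HF-Q replicate 8, and between -0.82 and -0.59 in the remaining 17. Without HF replicate 5 or HF replicate 11 the median was -0.21 or -0.14 (adjusted p = 0.0828 and 0.165), and on slides 1, 2 and 3 it was -1.73, 0.042 and 0.11, with -0.56 for the slide block. Of 9 erythroid markers, 7 were lower at a median of -0.097, with the haemoglobin gene Hba-a1 at -0.24 ± 0.12 (SE; camera adjusted p = 0.00711; adjusted p = 0.261 with an estimated correlation). Their median was -0.12 with the slide as a block and -0.087, -0.13 and -0.14 on slides 1, 2 and 3. Across all settings other than single arrays left out it ran from -0.18 to -0.034, and the camera adjusted p reached 0.529, so the call was not kept in all. Lists of Kupffer cell, lymphocyte, neutrophil, endothelial, bile duct, stellate cell and adipocyte markers did not pass.

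**Figure D3:**
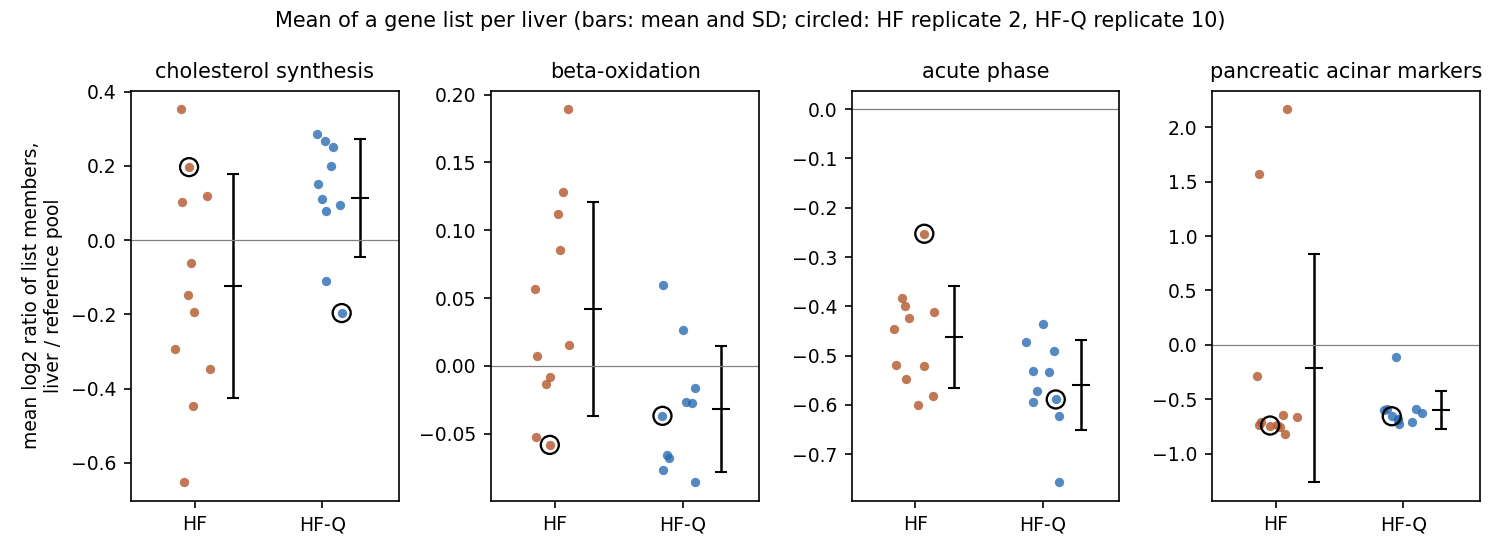
Mean log2 ratio to the reference pool over the members of 4 gene lists (vertical axis, a scale for each panel) in each HF and HF-Q liver, with the group mean and SD as bars and HF replicate 2 and HF-Q replicate 10 circled. The cholesterol synthesis means overlap between groups, every acute-phase mean lies below 0, and the pancreatic means stand out in 2 HF livers at 1.57 and 2.17.

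In all, 17 of 36 gene lists passed camera with the preset correlation of 0.01, 4 higher and 13 lower. Some lists share genes, as the CAR and PXR list and the female-biased list share Cyp2b9 and Cyp2b13. The 17 are therefore not 17 separate findings. None passed with an estimated correlation, where 5 had an unadjusted p under 0.05, and none passed fry, which tests whether the genes of a list move one way on balance. Of 100 simulated lists whose genes were correlated at 0.5 and did not differ between groups, 59% passed an unadjusted p of 0.05 with the preset correlation and 5% with an estimated one. Among the 17 lists only cholesterol synthesis (0.58) and the acinar genes (0.91) had an estimated correlation above 0.5. The others lay between 0.052 and 0.38, so the 59% does not describe them. All of these still exceed the preset 0.01, so the preset test may call them too readily as well. The rate at such correlations was not simulated. The other 19 lists did not pass. Their camera adjusted p values were 0.0605 for adipocyte markers, 0.0612 for inflammation and chemokines, 0.0700 for the circadian clock, whose median was -0.16, 0.0796 for stellate cells and fibrosis, 0.0809 for glucose metabolism, 0.101 for NRF2 antioxidant genes and 0.123 for omega-oxidation and acyl-CoA thioesterases. They were 0.247 for the cell cycle, 0.254 for bile duct markers, 0.350 for mitochondrial biogenesis, 0.471 for Kupffer cells, 0.486 for endothelial cells, 0.667 for bile acid and sterol transport and 0.698 for lymphocytes. Neutrophil markers, targets of the aryl hydrocarbon receptor, periportal markers and fatty acid synthesis each had 0.783, and interferon response genes had 0.950. Median, mean and test differed in sign for the neutrophil, aryl hydrocarbon receptor, periportal and interferon lists alone.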

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

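Chosen only after the results were seen were the tests of the slide for the Cyp2b genes, of dye bias and of the pool of livers, the counts with pairs of arrays left out, the splits that kept the slides balanced, and the search over exchanged pairs. In the HF-Q group, 88 genes and 17 list means were searched for a liver far from the other 9, by the gap to its neighbour over the range of the group. This picked out 18 of 105, where chance picks out about 1 in 20 groups, 5.25 here. The HF group has 11 livers and was not searched. HF-Q replicate 10 accounted for 12 of them: it stood high for Sult2a7 (0.49), Cyp2b10 (0.62), Cyp2b13 (0.39), Cyp2b9 (0.39), Decr1 (0.26), Hao2 (0.37), Sdhc (0.042) and the oxidative phosphorylation mean (0.060), and low for Gcat (-0.25), C6 (-0.61), Cyp4a12b (-1.10) and the male-biased mean (-0.58). HF-Q replicate 7 stood low for Amy2a5 (-0.59) and Rgn (-0.48). HF-Q replicate 8 stood high for Clps (-0.19), Cpa1 (-0.35) and the pancreatic mean (-0.11), and HF-Q replicate 1 stood low for the female-biased mean (-0.44).

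HF replicate 2 and HF-Q replicate 10 lay on the other group's side for Cyp2b9, Cyp2b10 and Cyp2b13. Slide was argued against as the source of the group difference, since the log2 fold change of Cyp2b10 was -1.42 with it as a block. For a shift of hepatocytes along the lobule, the pericentral median was -0.11, above the -0.3 set in advance, which argues only against a shift of that size. That list was itself lower in HF-Q in camera with the preset correlation, so a smaller shift stays open. Neither a group median nor a group fold change tells anything about the 2 single livers. Exchanged labels of these 2 livers remain a candidate explanation. On 200 other genes that parted the 19 remaining arrays, 16 of those 19 fell on their own side when left out in turn. HF replicate 2 scored 2.19 and HF-Q replicate 10 scored -2.85, each on the other side. The misplaced arrays among the 19 were HF replicates 1, 6 and 11, at 0.29, 0.68 and 0.72. The score thus placed HF livers less well than HF-Q livers, and says less about HF replicate 2. Without both livers 18 genes passed in limma against at most 3 for other pairs among 100 of the 110 possible, but the pair was picked by its Cyp2b levels, and a rule that picked the pair best parting any 1 gene chose HF replicate 11 and HF-Q replicate 10 instead, with 2 genes, as many as in 8 of 100 splits. Of the 16 of these genes other than Cyp2b, 13 placed HF replicate 2 and 15 placed HF-Q replicate 10 nearer to the other group. These genes passed once both livers were left out, which favours genes where these livers oppose the group difference. The count is therefore no independent sign of exchanged labels, and Fabp5, NAP111439-1 and NAP114472-1 among them had close values. Sult2a7 (0.23), Gm2990 (0.10) and Cebpe (-0.054) kept HF replicate 2 with its own group, and Cebpe (-0.066) also HF-Q replicate 10. Variation between animals stays open, and no array was relabelled.

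Cholesterol synthesis genes were higher in HF-Q at a median of 0.27. A single array was argued against by the lowest median with 1 array left out, 0.21, and slide by the median of 0.27 with it as a block. Of 100 splits of the arrays into groups of these sizes, 1, the real one, gave a median as far from 0, though another came to 0.2666 against 0.2667, and of 100 that kept the number of HF-Q arrays on each slide, 4 did, the real one included (highest other 0.31). With the preset correlation this list had the lowest camera p of all lists tested, but other splits were compared on this list alone. The counts of splits thus do not allow for its choice among the lists and decide nothing about an effect of quercetin. Such an effect on these genes may remain as a hypothesis. The adjusted p of 0.261 with an estimated correlation leaves open a variation between livers that these genes share.

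Some acute-phase genes lay far below the reference pool in both groups, while the median of all 17 in the list was -0.17: Saa2 at -3.13 ± 0.53 (SD, n = 21), Orm3 at -1.67 ± 0.26 and Lcn2 at -1.66 ± 0.18. A response in 1 of the 21 livers on arrays was argued against, since the highest log2 ratio of Lcn2, Orm2, Orm3, Saa1 and Saa2 on any array was -0.40. Dye bias of single probes and an acute-phase response in a liver that entered the pool but is not among the 21 arrays both stay open as candidate explanations. Their tests were made on the genes in which the pattern was seen, so the 0% of 10000 random lists of like intensity with a lower median than the acute-phase list, and the 5 of 24 acute-phase and neutrophil list members among 15 genes with a mean under -1 (one-sided Fisher's exact p = 5.78e-12), decide neither. The excluded livers were not analysed here, and no biological explanation between groups was tested.

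Other splits of the 21 arrays were drawn 100 times, the real one included. The real split called 17 lists, and 1 of 100 splits, the real one, gave as many (highest other 14, median 7). Such a count was thus uncommon among random splits, but 100 splits do not exclude chance. Nor does the count tell which lists differ. For genes past the adjusted threshold the count decides nothing, since the real split called 0, which all 100 splits must match (highest other 1). Chance was not excluded for the 1169 genes at an unadjusted p under 0.05, which 23 of 100 matched or passed (highest other 2912). These splits ignored the slide. Of 100 splits that kept the number of HF-Q arrays on each slide, 1, the real one, gave 17 lists (highest other 16), and 22 gave 1169 genes or more at an unadjusted p (highest other 2751). One of them passed 288 genes in limma, and 182 with the slide as a block, which points to a structure among the livers whose source was not tested.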

How the results depend on the processing

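The fits without HF replicate 2 and HF-Q replicate 10 together and the lists without the Cyp2b genes were chosen after seeing the data, and the others were planned. The count of genes past the adjusted threshold, 0 in limma, was 1 on slide 2 alone (Csad, named after its value was seen), 1 with array weights (Sult2a7), 18 without both livers, and 0 to 4 with 1 array left out. It stayed 0 under the other settings run. The 1169 genes at an unadjusted p were 239 with median centring, 1878 with no filter on dim probes, 708 on slide 2 alone, 1764 with array weights, 1869 without both livers, and 892 to 1544 with 1 array left out. The 17 lists were 7 on slide 2 and 9 on slide 3, 0 with an estimated correlation, 0 with fry, and 13 to 23 with 1 array left out. At thresholds of 0.10 and 0.01 they were 22 and 14. The oxidative phosphorylation median reversed to 0.045 with median centring, 0.013 in the deposited values and 0.015 on slide 1. On slide 2 the pancreatic, triglyceride and lipoprotein medians reversed to 0.042, 7.03e-04 and 0.020. On slide 3 the pancreatic, female-biased, stress response and male-biased ones reversed to 0.11, 0.064, -0.030 and -0.090. The cause was not tested, but a single slide holds fewer arrays, and its lists hold every member measured on it. Of the list values under other settings, 324 kept the call and the direction of the test, 74 lost the call and 10 reversed in the test. With median centring the lipoprotein and the CAR and PXR medians also changed sign, to 0.023 and 0.022, while the test did not. With 1 array left out 333 kept both and 24 lost the call. Across scalings the median of all genes lay between -0.0060 and 0.023. Aquantile leaves log ratios as they are and moved nothing. The replicate block gave 0 genes, 1129 at an unadjusted p and 16 lists. The 10 same-numbered pairs correlated at -0.34 to 0.16, 1 of them above 0.1 and 0 best with their own number, so the samples shared only a number. A scan date block was not run because it equals the slide. Of the 166 genes named by the rule, 102, 93 and 91 moved by over 1.5 times on slides 1, 2 and 3 alone (20, 17 and 14 turned direction), 56 with median centring (5 turned), 27 in the deposited values, 24 in the signals as processed by the scanner software, 22 without both livers (2 turned), 21 with Cy5 alone (4 turned) and at most 12 under any other setting.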

Other observations

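The test of ribosomal protein genes was chosen only after the result was seen. Outside the lists that passed, single members differed at an unadjusted p under 0.05, and those named here are not all of them. Over all genes 1169 of 19718 did so, against 985.9 that chance gives. Single members at such a p can thus arise by chance. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, had log2 fold changes of -0.63 ± 0.21 and -0.49 ± 0.20 (SE, n = 10 and 11), and Nfe2l2, which encodes NRF2, one of -0.13 ± 0.06. The bile acid receptor gene Nr1h4 differed by -0.20 ± 0.05, and the organic anion transporter gene Slco1a4 by -0.52 ± 0.18. Cdh1, which encodes E-cadherin and is a periportal marker, differed by 0.42 ± 0.14, and the antiviral gene Mx2 by 0.23 ± 0.08. None passed over all genes in limma (adjusted p between 0.685 and 0.809). Nr1h4 passed when adjusted over the list alone.

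Ribosomal protein genes were examined as a group after the results were seen, a hypothesis made from these data. Of 56 measured, 55 were higher in HF-Q, at a median log2 fold change of 0.065, and camera with an estimated correlation of 0.48 gave p = 0.0240, or 0.0140 with the slide as a block. The mean per liver was 0.020 ± 0.045 (SD, n = 10) in HF-Q and -0.048 ± 0.061 (n = 11) in HF. Under 8 other settings the median lay between 0.063 and 0.14 and p between 0.0126 and 0.147, the last with median centring. A small shared rise may be present, but the choice of the group after seeing the data makes these p values too small.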
